A study of Mus musculus with 8 samples.

How the data were processed

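Poly(A) RNA from mouse prefrontal cortex was sequenced in 8 libraries, per the labels: 3 from wild-type mice, 3 from saline-treated mice lacking exon 21 of 1 copy of Shank3, and 2 from such mice given the histone deacetylase inhibitor romidepsin. Per the labels' protocols the mice were males of 5 to 6 weeks. Romidepsin was given at 0.25 mg/kg once daily for 3 days and tissue was taken 1 day after the last dose. The labels name no treatment for the wild-type mice and do not say whether each library came from a separate animal.

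The deposited values are raw read counts per gene symbol, 1 table per library, with no normalization. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17.1.14, reads were aligned to the mm10/GRCm38 genome with TopHat2 2.1.1, and the authors counted reads per gene with HTSeq 0.6.1. The gene annotation and the strand setting of the counting are not given in the sources used here. Values were tested for being whole numbers, and libraries were tested pairwise for duplication. The counts of 7 libraries ended with the 5 summary entries that HTSeq writes. The table of saline replicate 1 lacked them and also lacked 1 gene, whose count was at most 1 elsewhere, so 24420 genes were common to all libraries. Counts on genes ranged from 7783538 to 15156318 per library. In the 7 libraries with summary entries, 32.4% to 35.3% of the counted alignments fell on genes, 48.0% to 49.3% on no annotated feature and 15.5% to 18.1% were not unique. Strandedness was checked on 7 genes with at least 90% of their exonic bases inside exons of a gene on the opposite strand. Their per-base counts were 0.864 of the overlapping gene's at the median, with 5 of 7 above 0.5, so counts of genes that overlap on opposite strands can mix.

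Expression was compared with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 14809 genes tested and 9611 removed. Libraries were scaled by the trimmed mean of M values (TMM). A robust quasi-likelihood model with a term per group was fitted to all 8 libraries, so that the 3 groups shared each gene's estimate of spread. The common biological coefficient of variation was 9.33%. Comparisons were saline-treated against wild type, romidepsin-treated against saline-treated, and romidepsin-treated against wild type. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (read counts scaled by TMM to a common library total), as means ± SD, and intervals of folds are at 95%. Log2 levels per library used a prior count of 2. The study's notes give no statistical model. The p-values measure only the spread between these libraries.

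The groups, comparisons, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Shank3, Hdac1, Hdac2, Hdac3 and Ctnnb1. It adds up to 10 genes per direction and comparison that passed, with a mean log2 CPM of at least 1 and groups that do not overlap. Where fewer passed, up to 5 genes with the smallest p were added, leaving out pseudogenes and unnamed predicted genes. It also takes, for moved-back genes, the 10 with the smallest larger p, and the 2 to 4 members with the smallest p of a list described. Other names were chosen after the values were seen. Coordinates are from the RefSeq annotation of GRCm38.p6, which placed 14162 of the tested symbols.

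Of 34 gene lists written from textbook knowledge, 32 had at least 5 tested members. No mitochondrially encoded gene was in the count tables, and of the red blood cell list too few members passed the filter, so neither list was tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. A list's library score is the mean over members of the log2 difference from the wild-type mean.

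The saline libraries enter both the first and the second comparison, which makes fold changes oppose each other by chance. Counts without any group difference were therefore simulated 50 times for the same design, and 25 times with each saline library left out. After the data were seen, the 2 comparisons were also fitted with separate saline libraries, 1 against romidepsin and the other 2 against wild type, in each of the 3 ways. On simulated data with the design and depth of these libraries, edgeR recovered 95.5% of genes changed 1.5-fold and 98.5% of genes changed 2-fold in saline against wild type. Recovery was 76.1% and 97.0% in romidepsin against saline. The changed genes were drawn only from genes with higher mean counts, so recovery of genes with low counts was not measured. Of the calls, 7.98% and 6.19% were false. A list raised 1.3-fold was recovered by camera, at an adjusted p of 0.0222 with an estimated correlation, with 0 of the other lists called. The simulated genes varied independently of each other, so this does not show how often camera calls lists of correlated genes falsely.

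Alternatives were relative log expression (RLE) size factors, library totals alone, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, only the groups compared, a block for the replicate number, other thresholds, and leaving out each library. Removing each library's trend with GC content and transcript length, known for 96.3% of tested genes, and joining both Shank3-deficient groups were added after the data were seen. Equal replicate numbers did not pair libraries: correlations of residuals within 7 such pairs ran from -0.261 to 0.158. The block therefore stayed an alternative.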

Results

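Gene expression in prefrontal cortex was measured in 3 groups of mice to ask how loss of part of Shank3 changes it and whether romidepsin, a histone deacetylase inhibitor, moves it back toward wild type. Shank3 encodes a scaffold protein of excitatory synapses, and the mutants carried a deletion of exon 21 in 1 copy. Wild type had 3 libraries, saline-treated Shank3-deficient mice (the saline group) 3, and romidepsin-treated Shank3-deficient mice (the romidepsin group) 2. Counts on genes were 12046120, 13280615 and 12460217 in the wild-type libraries, 15156318, 9640524 and 7783538 in the saline libraries, and 10143846 and 9855883 in the romidepsin libraries. Between 16993 and 17763 genes had at least 1 read per library. Rn45s, the ribosomal RNA precursor, took 1.12% of counts in saline replicate 2 and 0.316% to 0.611% in the other libraries. On the first principal component, with 29.3% of the variance, wild-type libraries scored -4.45, 6.17 and 22.4, saline libraries 1.95, -25.3 and -1.11, and romidepsin libraries 1.33 and -1.04.

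Shank3 (chromosome 15, 89493013 to 89560261, GRCm38) was read at similar levels in all groups. Its normalised read count (CPM, scaled to a common library total) was 319 ± 26.1 (SD, n = 3) in wild type, 290 ± 33.7 (n = 3) in the saline group and 314 ± 1.86 (n = 2) in the romidepsin group. The saline group was at 0.910-fold of wild type (95% interval 0.795 to 1.04), and the romidepsin group differed from the saline group by a log2 fold change of 0.11 (SE 0.10). Neither passed the edgeR quasi-likelihood test (adjusted p = 0.724 and 1.00). The log2 fold change of the saline group from wild type, -0.14, was -0.04 without saline replicate 2, -0.21 without saline replicate 1 and -0.07 without wild-type replicate 3. That of the romidepsin group from the saline group was 0.02 without saline replicate 2 and 0.18 without saline replicate 1. The interval excluded a fall to 1 functional copy's dose in whole-gene counts, but reads on the remaining exons of the deleted copy are counted too, so gene-level counts do not check the genotype. Among the drug's targets, Hdac1 stood at 23.9 ± 0.436, 24.0 ± 1.34 and 21.6 ± 2.82 CPM in wild type, saline and romidepsin. Hdac2 stood at 71.2 ± 7.38, 73.5 ± 3.70 and 76.3 ± 3.06, and Hdac3 at 73.2 ± 2.11, 65.8 ± 5.72 and 72.3 ± 4.75. The direction of the smallest differences, in Hdac1 and Hdac2, reversed in some alternative settings. Ctnnb1, which encodes beta-catenin, stood at 545 ± 18.6, 612 ± 8.44 and 570 ± 5.47. None of these 4 genes passed in either comparison (smallest adjusted p = 0.533, Ctnnb1 in saline against wild type).

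**Figure D1:**
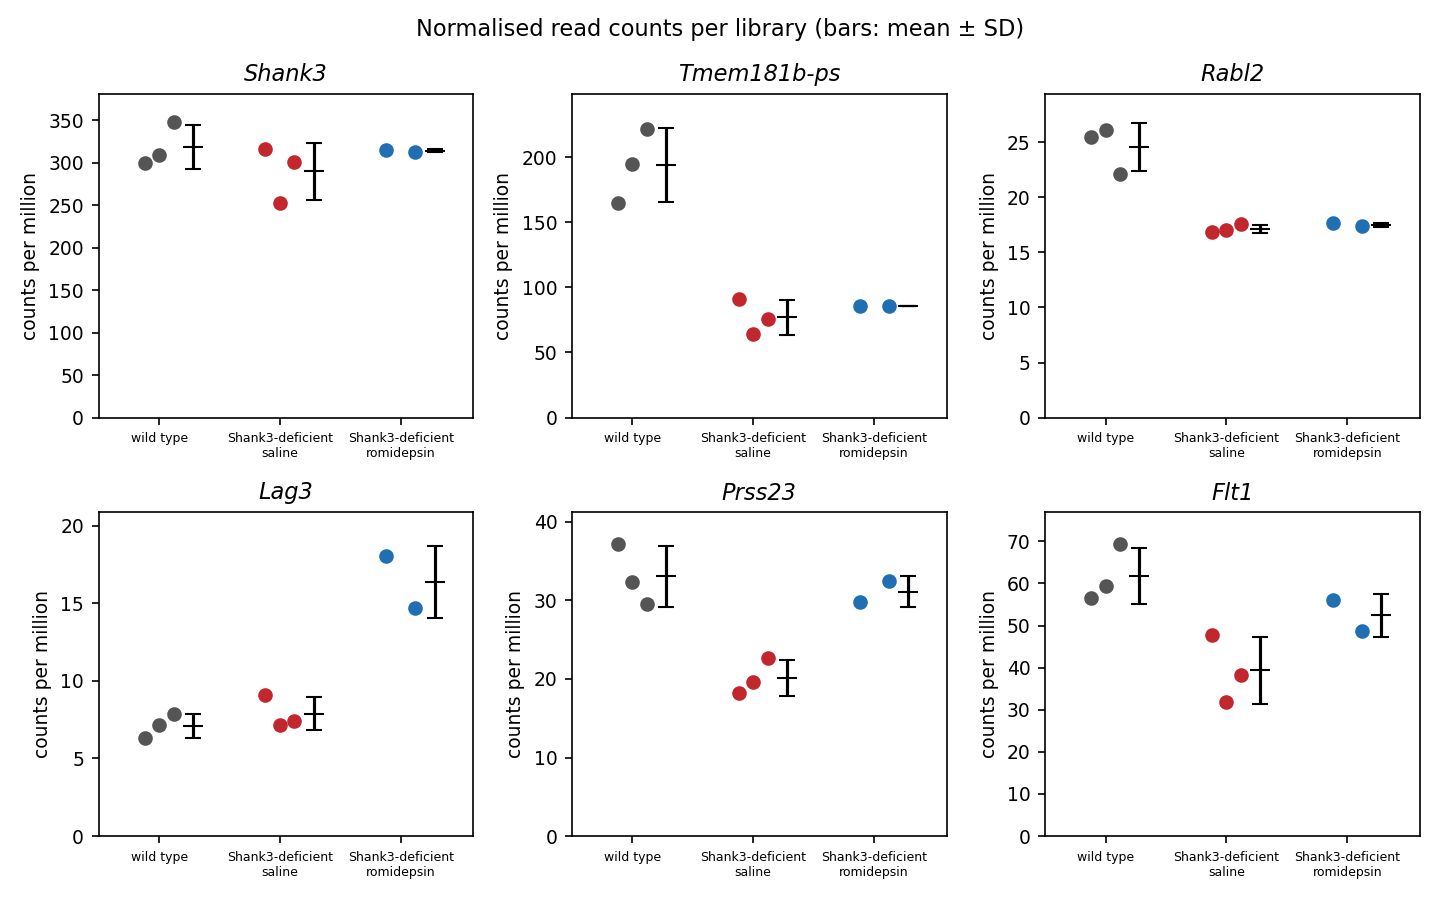
Normalised read counts (CPM) of 6 genes in each library (points) with the mean and SD of each group (bars), each axis starting at 0. Tmem181b-ps averaged 194 in wild type and 76.9 and 85.6 in the saline and romidepsin groups, while Shank3 averaged 319, 290 and 314.

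Loss of part of Shank3 was addressed by the saline group against wild type. Since the labels name no treatment for the wild-type mice, an effect of the saline treatment cannot be told apart from that of the genotype. Tmem181b-ps, a transcribed pseudogene related to the transmembrane protein gene Tmem181a (chromosome 17, 6439002 to 6450994), fell from 194 ± 28.6 CPM (n = 3) to 76.9 ± 13.7 (n = 3). This was a 0.398-fold level (95% interval 0.329 to 0.483; adjusted p = 0.00215), and all 3 saline libraries lay below all 3 wild-type libraries. It was the only gene of 14809 to pass, with 0 higher and 1 lower, and it passed again in all 17 alternative settings. Cbfa2t3, a transcriptional corepressor gene, stood at 58.5 ± 1.83 and 39.9 ± 2.25 CPM, below the threshold of the test (log2 fold change -0.55, adjusted p = 0.0771). Tanc1, a postsynaptic scaffold gene, stood at 23.6 ± 1.94 and 13.8 ± 0.347 (log2 fold change -0.78). Prss23, a serine protease gene, stood at 33.1 ± 3.88 and 20.2 ± 2.30 (log2 fold change -0.72, adjusted p = 0.0797 for both). Banp, a nuclear matrix gene, at 37.5 ± 3.36 and 22.9 ± 3.60, and Tmem181a, at 71.7 ± 1.52 and 53.6 ± 3.22, also came short (adjusted p = 0.101 and 0.164). On the higher side, Gm3893, a transcribed pseudogene chosen after its values were seen, stood at 6.08 ± 0.734 and 20.6 ± 3.99 (log2 fold change 1.76, adjusted p = 0.164). It passed in 5 of 17 alternative settings, among them DESeq2 (adjusted p = 3.42e-08), only the 2 groups fitted (0.00367) and without romidepsin replicate 1 (0.00307) or 2 (0.00234), in a range up to 0.652. Leaving out pseudogenes and unnamed predicted genes, the smallest p on that side were those of the neuronal gene Nrep, at 56.9 ± 4.16 and 74.4 ± 0.883 (adjusted p = 0.187), and the synapse organizer Cbln1, at 7.38 ± 0.782 and 12.7 ± 2.02 (adjusted p = 0.190). Behind them came the transporter gene Slc47a1, the kinase gene Sik1 and the G protein subunit gene Gng4 (log2 fold changes 1.85, 0.54 and 0.41). These last 11 genes were separated without overlap in 3 against 3 libraries. They were picked by a small p or after their values were seen, which makes such separation likely, so it adds no support.

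At an unadjusted p under 0.05 there were 1242 genes (531 higher, 711 lower), where independent genes would give 740 by chance. Other splits of the same 6 libraries into 3 against 3 gave up to 1707 genes, and 4 of the 10 splits, the real one included, gave at least 1242. Groups did not overlap in 12.6% of genes, where chance gives 10%. DESeq2 called 31 genes, 4 higher and 27 lower, among them Cbfa2t3, Prss23, Banp, Tanc1, Flt1, Nefh, Nr4a1 and Nrep, while limma-voom called Tmem181b-ps alone. Without wild-type replicate 3 the count was 54 (8 higher, 46 lower), with Homer1, Egr3, Nefh and Baiap2 lower. It was 9 without saline replicate 1 and 3 without saline replicate 3. Rabl2, which lies 22.3 kb from Shank3, was chosen after its values were seen: it stood at 24.6 ± 2.2 CPM in wild type, 17.2 ± 0.373 in the saline group and 17.5 ± 0.172 in the romidepsin group (adjusted p = 0.190 for the saline group).

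Vessel markers were lower, and meningeal and olfactory markers higher, on average in the saline group than in wild type, with libraries of both groups overlapping on all 3 lists. The endothelial growth factor receptor gene Flt1 stood at 61.8 ± 6.73 CPM in wild type and 39.3 ± 8.03 in the saline group, the junction gene Pecam1 at 22.9 ± 3.15 and 14.8 ± 3.06, and the pericyte gene Rgs5 at 52.3 ± 4.91 and 39.9 ± 4.15. Of the 20 endothelial and pericyte markers, 14 were lower, with a median log2 fold change of -0.29 (camera adjusted p = 9.42e-05, but adjusted p = 0.800 with an estimated correlation). Adjusted over the list alone 8 of them passed, and 0 over all genes. The median was -0.18 without wild-type replicate 3 and -0.43 without saline replicate 1, both called. All 15 meningeal and fibroblast markers were higher at the median by 0.68 (camera adjusted p = 4.27e-05, and adjusted p = 0.800 with an estimated correlation), for example the fibroblast gene Islr, at 10.8 ± 2.28 and 16.2 ± 1.34. Islr alone passed adjusted over the list alone. The list's score was 1.05, 0.83 and -0.14 in the 3 saline libraries, and without saline replicate 1 its median was 0.43. Of 13 olfactory bulb and septal markers 12 were higher, with a median of 0.54 (camera adjusted p = 0.00414, and adjusted p = 0.800 with an estimated correlation). Trh, a releasing hormone gene that passed adjusted over the list alone, stood at 1.21 ± 0.446 and 3.74 ± 1.59, and Eomes, a transcription factor gene, at 0.551 ± 0.338 and 2.93 ± 2.48. The olfactory call ended without wild-type replicate 1 (median 0.40, adjusted p = 0.0802) and without wild-type replicate 2 (median 0.29, adjusted p = 0.0797). Its median was 1.02 without wild-type replicate 3, 0.31 without saline replicate 1 and 0.35 without saline replicate 3. How much meningeal or olfactory tissue each sample held was not measured apart from these transcripts.

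Ribosomal, respiratory and cholesterol synthesis genes stood slightly higher in the saline group, and protein folding genes lower. Cytosolic ribosomal protein genes were higher in 50 of 52 (median log2 fold change 0.08, camera adjusted p = 4.27e-05, but 0.800 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were higher in 46 of 62 (median 0.05, adjusted p = 0.0288, but 0.856 with an estimated correlation) and cholesterol synthesis genes in 21 of 24 (median 0.12, adjusted p = 0.000815, but 0.800). The cholesterol list included the thiolase gene Acat2, at 22.4 ± 1.21 and 27.2 ± 1.55 CPM. Heat shock and unfolded protein genes were lower in 18 of 23 (median -0.15, adjusted p = 0.00405, but 0.800 with an estimated correlation), including the endoplasmic reticulum genes Sdf2l1, at 18.2 ± 5.06 and 11.7 ± 1.3, and Manf, at 59.8 ± 7.47 and 45.9 ± 4.42. Of these 4 lists 0 members passed adjusted over the list alone. The ribosomal call ended without wild-type replicate 2 (median 0.03), with a median of 0.13 without wild-type replicate 3, and the cholesterol call ended without saline replicate 3 (median 0.06). The heat shock call ended without wild-type replicate 2 (median -0.09), saline replicate 1 (-0.13) or saline replicate 3 (-0.08), and its median was -0.29 without saline replicate 2. The oxidative phosphorylation call ended without wild-type replicate 2 (0.06), wild-type replicate 3 (0.0012), saline replicate 2 (0.02) or saline replicate 3 (0.03), and its median was 0.08 without wild-type replicate 1 or saline replicate 1.

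Synaptic and activity genes gave no list call between saline and wild type. Among immediate early genes, which neuronal firing induces, 4 passed adjusted over the list alone and 0 over all genes. These were Sik1 at 16.1 ± 1.41 and 23.7 ± 3.77 CPM, Nr4a1 at 124 ± 13.7 and 169 ± 23.0, Dusp1 at 34.0 ± 1.27 and 49.4 ± 10.7, and Fos at 43.2 ± 4.33 and 60.9 ± 12.5. The list of 34 was higher in 20 (median 0.07, camera adjusted p = 0.10). Its members Egr3, Homer1 and Nptx2 were called lower without wild-type replicate 3 (log2 fold changes -0.51, -0.45 and -0.42). Actin regulators, which shape dendritic spines, were lower in 49 of 90 (median -0.02, adjusted p = 0.476), and the nonmuscle myosin gene Myh9, at 136 ± 6.16 and 106 ± 8.47, alone passed adjusted over the list alone. Postsynaptic scaffold genes were lower in 21 of 39 (adjusted p = 0.998), glutamate receptor genes higher in 20 of 30 (adjusted p = 0.275) and GABA genes higher in 15 of 19 (adjusted p = 0.248). Of 42 voltage-gated ion channel genes 28 were lower (adjusted p = 0.0826), and 1 of the lower ones passed adjusted over the list alone. The test fry, which asks whether a list's genes move on balance in 1 direction, called 0 of 32 lists (smallest adjusted p = 0.0570, for thalamic and hypothalamic markers).

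**Figure D2:**
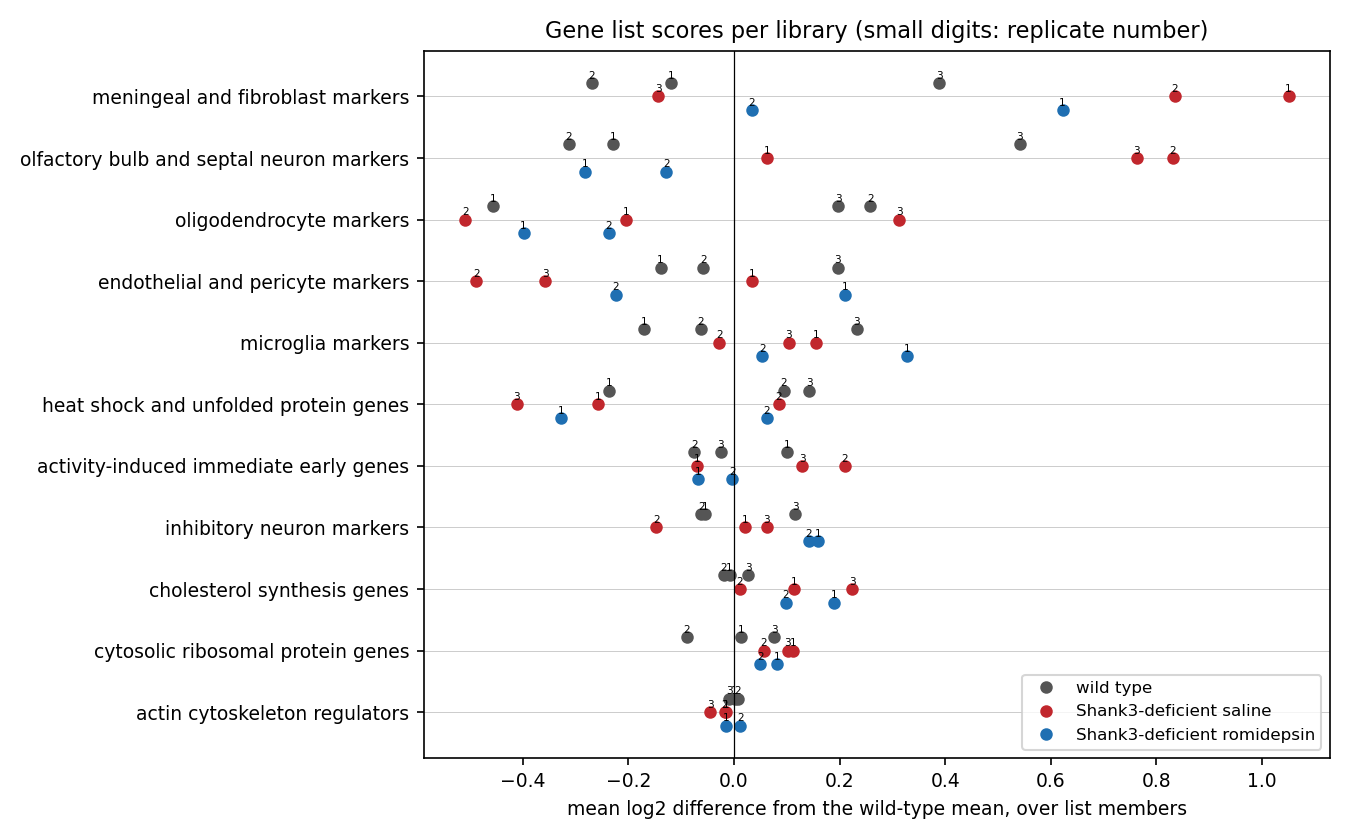
List scores of each library, as the mean log2 difference of a list's members from the wild-type mean. Shown are some of the gene lists called in at least 1 comparison, and actin cytoskeleton regulators, which were called in none. Endothelial and pericyte markers averaged -0.27 in the saline group and -0.0065 in the romidepsin group, with libraries of 1 group lying apart.

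Romidepsin against saline asked what the drug changed in the mutants, and no gene passed. Lag3, an immune checkpoint receptor gene, had the smallest p: it stood at 7.89 ± 1.07 CPM in the saline group (n = 3) and 16.4 ± 2.34 in the romidepsin group (n = 2), a log2 fold change of 1.04 (SE 0.18; adjusted p = 0.602). Prss23 stood at 20.2 ± 2.30 and 31.1 ± 1.96, the amino acid transporter gene Slc7a5 at 52.0 ± 5.76 and 71.6 ± 4.41, and the neurofilament gene Nefh at 41.4 ± 2.78 and 58.7 ± 4.16. On the lower side, the astrocyte enzyme gene Etnppl stood at 22.8 ± 5.69 and 11.3 ± 0.563, and Fos at 60.9 ± 12.5 and 40.7 ± 0.668. The matrix gene Thbs2 stood at 10.5 ± 0.245 and 6.94 ± 0.0708, and the transcription regulators Lcorl at 32.6 ± 2.88 and 23.3 ± 2.91 and Zfpm2 at 28.2 ± 5.06 and 18.3 ± 2.63. These 8 genes after Lag3 had adjusted p = 1.00. The count was 0 in edgeR, DESeq2 and limma-voom, with 483 genes at an unadjusted p under 0.05 (256 higher, 227 lower) where chance gives 740, and 20.9% of genes without overlap, where chance gives 20%. Without saline replicate 1 the count was 3, and without romidepsin replicate 1 it was 3.

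Vessel and interneuron transcripts were higher under romidepsin as lists, and olfactory and activity transcripts lower. The saline libraries also serve the comparison with wild type, where vessel markers were lower and olfactory markers higher. Those opposite directions are therefore not separate observations. Of 20 endothelial and pericyte markers 19 were higher than in the saline group (median 0.29, camera adjusted p = 0.000227, but 0.847 with an estimated correlation), with Flt1 at 39.3 ± 8.03 and 52.4 ± 5.15 CPM and the potassium channel subunit gene Abcc9 at 7.85 ± 1.60 and 12.8 ± 1.46. The call ended without romidepsin replicate 1 (median 0.11, adjusted p = 0.217), and the median was 0.44 without saline replicate 1 and 0.14 without saline replicate 2. Of 20 inhibitory neuron markers 17 were higher (median 0.15, adjusted p = 0.00160, but 0.802 with an estimated correlation), including the interneuron transcription factor gene Lhx6, at 21.0 ± 2.64 and 28.2 ± 0.229, and the neuropeptide gene Npy, at 65.7 ± 8.61 and 82.7 ± 2.40. This call, at the preset correlation, held with each library left out. GABA receptor and synthesis genes, a list that shares members with it, were not higher, with mean scores of 0.034 in the saline group and 0.016 under romidepsin. Of 13 olfactory and septal markers 12 were lower (median -0.79, adjusted p = 0.000991, but 0.802 with an estimated correlation), for example Eomes at 2.93 ± 2.48 and 0.101 ± 0.0031, and the median was -0.50 without saline replicate 1. No member of any list passed adjusted over the list alone or over all genes, and fry called 0 lists (smallest adjusted p = 0.234).

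Channel, presynaptic and activity genes were also called between romidepsin and saline. Voltage-gated ion channel genes were higher in 31 of 42 (median 0.09, camera adjusted p = 0.00223, but 0.847 with an estimated correlation), with the fast-spiking potassium channel gene Kcnc1 at 175 ± 14.9 and 211 ± 6.51 CPM. Presynaptic vesicle genes were higher in 23 of 32 (median 0.08, adjusted p = 0.0237, but 0.847 with an estimated correlation), with the active zone gene Bsn at 723 ± 21.2 and 849 ± 38.3. Immediate early genes were lower in 23 of 34 (median -0.09, adjusted p = 0.0203, but 0.847 with an estimated correlation), with Nr4a1 at 169 ± 23.0 and 132 ± 4.28. Striatal markers were higher in 11 of 17 (median 0.18, adjusted p = 0.0329, but 0.802 with an estimated correlation), with the GTPase gene Rasd2 at 52.9 ± 1.55 and 65.5 ± 6.43. Microglia markers were higher in 14 of 16 (median 0.11, adjusted p = 0.0496, but 0.856 with an estimated correlation), with the protease gene Ctss at 65.7 ± 0.772 and 80.1 ± 8.49. Each of these 5 calls ended when 1 of several libraries was left out. The channel call ended without saline replicate 1 (median 0.09) or romidepsin replicate 2 (0.05), and the presynaptic call without the same libraries (0.06 and 0.06). The early gene call ended without saline replicate 2 (-0.09), saline replicate 3 (-0.09) or romidepsin replicate 1 (-0.05), and its median was -0.17 without saline replicate 1 and -0.15 without romidepsin replicate 2. The striatal call ended without saline replicate 1 (0.11), saline replicate 3 (0.08) or romidepsin replicate 1 (0.09), with a median of 0.10 without saline replicate 2. The microglia call ended without wild-type replicate 2 (0.11), saline replicate 2 (0.06), saline replicate 3 (0.12) or romidepsin replicate 1 (-0.05), with a median of 0.23 without romidepsin replicate 2. Genes that histone deacetylase inhibitors raise in other cells were higher in 4 of 15 (median -0.08, adjusted p = 0.0503).

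No gene met the definition of changed in the saline group and moved back under romidepsin, which required both tests to pass. Prss23 came nearest, at 33.1 ± 3.88 CPM in wild type, 20.2 ± 2.30 in the saline group and 31.1 ± 1.96 in the romidepsin group. Nefh stood at 59.9 ± 10.9, 41.4 ± 2.78 and 58.7 ± 4.16, the metalloprotease gene Adam19 at 40.8 ± 7.69, 27.1 ± 1.17 and 38.2 ± 1.39, and the collagen gene Col4a2 at 82.5 ± 8.29, 55.9 ± 10.6 and 78.0 ± 0.907. Myh9 stood at 136, 106 and 130, and Banp at 37.5, 22.9 and 31.4. In the other direction Thbs2 stood at 6.88 ± 0.106, 10.5 ± 0.245 and 6.94 ± 0.0708, Fos at 43.2, 60.9 and 40.7, Lcorl at 24.6, 32.6 and 23.3, and the transcription factor gene Tshz2 at 27.5, 35.9 and 27.1. The count was 0 by edgeR, DESeq2 and limma-voom, and 3 without saline replicate 1 (Rap1gap2, Wdfy1 and Eomes, the first 2 chosen after their values were seen).

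At an unadjusted p under 0.05 in both comparisons, 197 genes had opposite signs (71 higher in saline then lower, 126 lower then higher) and 1 the same sign. Independent lists of these sizes would share 8.14 and 12.3, but the saline libraries serve both comparisons, and simulated data without any effect gave 129 (range 100 to 151). The simulated genes varied independently of each other, so real libraries can spread more widely than this range. Regroupings of the 8 libraries keep the correlation between genes. With limma on log2 CPM the real grouping gave 218 such genes and the others 11 to 346. Of 100 regroupings, the real one included, 17 gave at least as many, and 16 had a Pearson correlation at least as negative. Across genes the log2 fold changes correlated at -0.51 (Pearson; simulated mean -0.45, range -0.49 to -0.41) and their covariance was -0.0354 (simulated -0.0245), genes not being independent replicates. Of the 1242 genes at an unadjusted p under 0.05 in saline against wild type, 91.9% had the opposite sign under romidepsin, against 87.2% in simulations. Without saline replicate 2 the 197 became 120, below the simulated 169. It became 308 without saline replicate 1 (simulated 176) and 301 without saline replicate 3 (simulated 167). No library served both comparisons when 1 saline library was set against romidepsin and the other 2 against wild type. The correlation was then -0.06, -0.17 and 0.06 with saline replicates 1, 2 and 3 set against romidepsin. Opposite signs at an unadjusted p under 0.05 in both numbered 26, 147 and 41 genes, and the same sign 4, 20 and 53, the lone library being assumed to vary like the others.

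**Figure D3:**
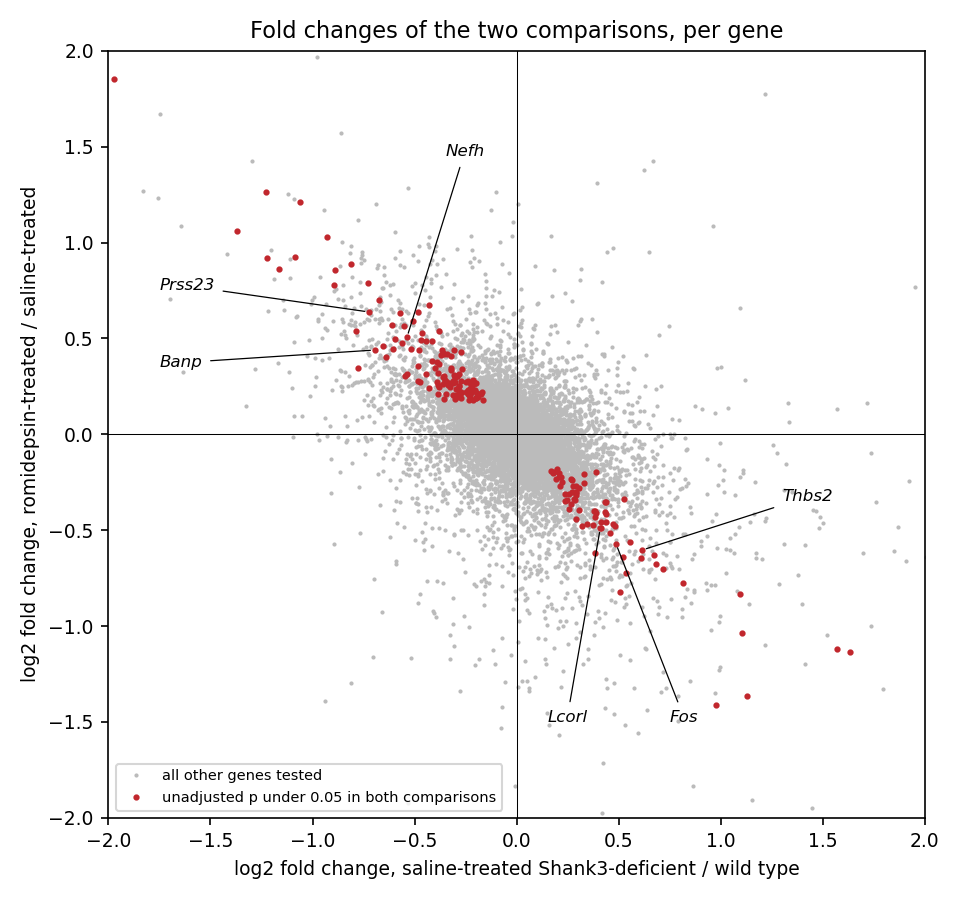
Log2 fold changes of each gene in romidepsin against saline (vertical) and saline against wild type (horizontal), for 14786 genes within the axes, with 23 outside. The 198 genes in red had an unadjusted p under 0.05 in both, and 197 of them had opposite signs.

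The romidepsin group was also compared with wild type. The same 3 wild-type libraries serve the comparison of the saline group, so differences found in both are not independent of each other. Tmem181b-ps was again lower, at 85.6 ± 0.0691 CPM (n = 2) against 194 ± 28.6 (n = 3), a 0.441-fold level (95% interval 0.355 to 0.549; adjusted p = 0.0344), with both romidepsin libraries below all 3 wild-type libraries. Its call ended without wild-type replicate 2 (adjusted p = 0.15), wild-type replicate 3 (0.0532), saline replicate 3 (0.0533), romidepsin replicate 1 (0.195) or romidepsin replicate 2 (0.388), over a range of 1.45e-12 to 0.388 in 17 settings, while its log2 fold change stayed between -1.29 and -1.08. Lag3 stood at 16.4 ± 2.34 against 7.10 ± 0.762, 2.30-fold (adjusted p = 0.0567), and passed in 4 of 17 alternative settings. These were DESeq2 (adjusted p = 0.00116), no filter (0.00826), without wild-type replicate 3 (0.0392) and a GC and length correction chosen after the data were seen (0.0311), in a range up to 0.799. The clock gene Dbp stood at 61.2 ± 4.80 against 39.2 ± 4.20 (adjusted p = 0.661). These 3 names were chosen after their values were seen in this comparison. Tmem181b-ps was the only gene to pass (0 higher, 1 lower), with 480 at an unadjusted p under 0.05 where chance gives 740, and 18.4% of genes without overlap, where chance gives 20%. DESeq2 called 4 genes and limma-voom 1. The count was 0 without wild-type replicate 2 or saline replicate 3, 2 without wild-type replicate 3 and 3 without romidepsin replicate 1.

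As lists, cholesterol synthesis genes were higher in 24 of 24 in the romidepsin group than in wild type (median 0.13, camera adjusted p = 4.18e-06, but 0.968 with an estimated correlation), with Acat2 at 26.7 ± 0.814 and 22.4 ± 1.21 CPM. Inhibitory neuron markers were higher in 18 of 20 (median 0.14, adjusted p = 0.000534, but 0.968 with an estimated correlation), with Lhx6 at 28.2 ± 0.229 and 22.6 ± 0.937. The call, at the preset correlation, held with each library left out. Oligodendrocyte markers were lower in 17 of 17 (median -0.31, adjusted p = 0.000467, but 0.968 with an estimated correlation), with the myelin gene Opalin at 7.34 ± 0.770 and 11.8 ± 2.89. The list's score was -0.318 ± 0.114 in the romidepsin group and 0 ± 0.396 in wild type, so the wild-type libraries spread widely. Microglia markers were higher in 15 of 16 (median 0.20, adjusted p = 0.000427, but 0.968 with an estimated correlation), with the receptor gene Trem2 at 14.7 ± 4.67 and 10 ± 1.13. Ribosomal protein genes were higher in 43 of 52 (median 0.08, adjusted p = 0.000493), meningeal markers in 15 of 15 (median 0.30, adjusted p = 0.00947) and presynaptic genes in 27 of 32 (median 0.06, adjusted p = 0.0196). With an estimated correlation the adjusted p of these last 3 lists was 0.968 too. Adjusted over the list alone Dbp and Penk, an opioid peptide gene at 41.5 ± 1.21 and 29.1 ± 3.98, passed within lists that were not called. Without romidepsin replicate 1 the calls ended on cholesterol (median 0.11), microglia (0.02), oligodendrocyte (-0.20), ribosomal (0.04), meningeal (0.01) and presynaptic lists (0.08). Calls also ended without wild-type replicate 1 (microglia 0.11, meningeal 0.21), wild-type replicate 2 (oligodendrocyte -0.18, ribosomal 0.02, meningeal 0.20), wild-type replicate 3 (oligodendrocyte -0.21, presynaptic -0.0060) or romidepsin replicate 2 (presynaptic 0.05). Medians moved while still called without wild-type replicate 1 (oligodendrocyte -0.52, presynaptic 0.15) and wild-type replicate 3 (inhibitory 0.22, meningeal 0.57). They also moved without romidepsin replicate 2 (cholesterol 0.21, microglia 0.30, oligodendrocyte -0.48, meningeal 0.63).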

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

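The correction for GC content and transcript length and the joining of both Shank3-deficient groups were chosen after the results were seen, and the other alternatives were planned. Tmem181b-ps passed in saline against wild type in all 17 settings (log2 fold change -1.48 to -1.21), and in 10 of 17 in romidepsin against wild type. The number of genes changed in saline against wild type, 1 as reported, was 12 without a filter, 31 with DESeq2, 2 with only the groups compared, 4 with a block for the replicate number, 4 at an adjusted p under 0.10, and 858 at an unadjusted p under 0.05 with a 1.2-fold change. Leaving out 1 library gave 1 to 54. Romidepsin against saline, 0 as reported, gave 361 at the unadjusted threshold and 0 to 3 with 1 library left out. Romidepsin against wild type, 1 as reported, gave 0 with library totals alone, 2 without a filter, 4 with DESeq2, 0 with the block, 2 after the GC and length correction, 2 at an adjusted p under 0.10, 389 at the unadjusted threshold and 0 to 3 with 1 library left out. Genes moved back, 0 as reported, numbered 128 at the unadjusted threshold and 0 to 3 with 1 library left out. The correlation of fold changes stayed negative, from -0.65 to -0.41 with 1 library left out. Both Shank3-deficient groups together against wild type called Tmem181b-ps alone. The looser thresholds raise counts by construction, and for the other differences the cause was not tested.

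Of 2489 recomputed values for 147 fold changes of named genes, 2423 kept their direction and side of the threshold, 51 came to pass, 7 ceased to pass and 8 reversed. Of 352 for 22 list calls, 298 were kept, 52 ceased and 2 reversed. Hdac1 in saline against wild type ran from -0.035 to 0.049 with 1 library left out and was -0.018 after the GC and length correction. Hdac2 ran from -0.040 to 0.10 there and was -0.0070 in romidepsin against saline with the block for pairing. Without romidepsin replicate 1, Tyrobp in romidepsin against saline reversed (range -0.074 to 0.45), as did Col3a1 in romidepsin against wild type (-0.19 to 1.01) and the microglia median in romidepsin against saline (-0.054 to 0.23). Shank3 moved to -0.02 and 0.02 in saline against wild type and romidepsin against saline after the GC and length correction. That correction ended the calls on oxidative phosphorylation genes in saline against wild type (median 0.015) and on channel, presynaptic and striatal genes in romidepsin against saline (0.07, 0.04 and 0.13). The block for pairing ended the same 4 calls (0.05, 0.08, 0.04 and 0.17) and, in romidepsin against wild type, those on oligodendrocyte (-0.13), meningeal (0.27) and presynaptic genes (0.04) and on Tmem181b-ps (log2 fold change -1.13). In romidepsin against saline the striatal (0.17) and microglia calls (0.11) ended without a filter, and with library totals alone the microglia call (0.10) and, in romidepsin against wild type, Tmem181b-ps (-1.20). The presynaptic median in romidepsin against wild type ran from -0.0060 to 0.15, negative without wild-type replicate 3. The cause was not tested. With a group reduced to 1 library, that library was assumed to vary like the other groups. The planned exclusion of mitochondrially encoded genes was not run, since none is in the count tables. Simulated 2-fold changes were recovered in both main comparisons, but only in genes with higher counts and among many changed genes, which eases the adjusted threshold. Lag3, 2.05-fold higher under romidepsin than under saline, did not pass, so single changes of about 2-fold can go uncalled in these libraries.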

Other observations

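The correction for GC content and transcript length, the joining of both Shank3-deficient groups, which the test of genes around Shank3 uses, and the test with separate saline libraries were chosen after the data were seen, and the patterns weighed were noticed in these data. Clock genes differed between the groups in some members. Arntl, which drives the clock, stood at 48.5 ± 1.47 CPM in wild type, 38.0 ± 3.42 in the saline group and 40.2 ± 3.67 in the romidepsin group. Its targets Dbp, at 39.2 ± 4.20, 52.1 ± 7.37 and 61.2 ± 4.80, and Ciart, at 6.78 ± 0.844, 10.2 ± 0.993 and 9.49 ± 1.57, stood the other way. These 3 genes passed in saline against wild type adjusted over the list alone, and 0 passed over all genes. The list as a whole was not called (camera adjusted p = 0.998). Camera tests a shift in 1 direction, so it can miss a list whose members move in opposite directions. The form of fry that asks for changes in either direction called 0 of 32 lists in that comparison (smallest adjusted p = 0.117). The hour at which tissue was taken is not given in the sources used here. Among chromatin regulators the demethylase gene Tet3, at 106 ± 5.35, 86.7 ± 5.90 and 99.7 ± 3.00, was 1 of 2 lower members that passed adjusted over the list alone in saline against wild type. The list was lower in 32 of 56 (adjusted p = 0.187). Histone deacetylase genes were lower in 13 of 18 (adjusted p = 0.189), and Sirt4, a mitochondrial sirtuin gene at 16.9 ± 2.32, 11.1 ± 1.92 and 13.1 ± 1.04, passed adjusted over the list alone.

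Thalamic and hypothalamic markers were higher in 7 of 10 in saline against wild type (camera adjusted p = 0.0826), with Trh, Ramp3, Calb2 and Slc17a6 passing adjusted over the list alone. Ramp3, a receptor subunit gene, stood at 21.0 ± 3.32 CPM in wild type, 29.3 ± 2.25 in the saline group and 24.6 ± 0.525 in the romidepsin group. Of the remaining lists, none was called in saline against wild type: autism risk genes were higher in 26 of 49 (adjusted p = 0.998), Wnt pathway genes in 20 of 37 (0.960), excitatory neuron markers in 13 of 22 (0.593), interferon-induced genes in 10 of 18 (0.992) and glucocorticoid-responsive genes in 11 of 20 (0.998, with Dusp1 passing adjusted over the list alone). The genes of PI3K, mTOR and MAPK signalling were lower in 21 of 40 (0.666), astrocyte markers in 9 of 15 (0.893), oligodendrocyte precursor markers in 7 of 12 (0.599), and choroid plexus markers higher in 4 of 5 (0.294). In romidepsin against saline the adjusted p of these lists was 0.412, 0.546, 0.433, 0.433 and 0.868, then 0.446, 0.729, 0.260 and 0.0727, in the same order. Rap1gap2, a regulator of the small GTPase Rap, was chosen after its values were seen. It stood at 484, 452 and 391 CPM in wild type, 499 and 470 under romidepsin and 449 in saline replicate 1, but at 42.3 and 37.6 in saline replicates 2 and 3. Its log2 fold change in saline against wild type was -1.30 (SE 1.02, adjusted p = 0.788) and -3.47 without saline replicate 1.

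Fold changes of the first 2 comparisons opposed each other. The shared saline libraries may account for most of this, since 8 of 100 regroupings of the libraries, the real grouping included, gave a covariance at least as negative, and simulated data without any effect gave a correlation of -0.45 against the -0.51 observed. The excess of opposing genes over simulation was not seen without saline replicate 2. Without that library, genes at an unadjusted p under 0.05 in both with opposite signs numbered 0.712 of the simulated number, against 1.75 and 1.80 without saline replicates 1 and 3. The covariance without it was -0.0365, against a simulated -0.0345. The simulated genes varied independently of each other, and 17 of 100 regroupings, the real one included, gave at least as many such genes. An excess over chance was therefore not established. A partial return toward wild type under romidepsin stays open: with 2 saline libraries against wild type and the third against romidepsin, the covariance averaged over the 3 divisions was -0.0058, and 19 of 100 regroupings were at least as negative.

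Endothelial and pericyte markers were lower in the saline group and higher under romidepsin by camera with a preset correlation, but neither was called with an estimated correlation (adjusted p = 0.800 and 0.847). Both calls use the same saline libraries, whose mean score was -0.27, against 0 in wild type and -0.0065 under romidepsin. A low score of the saline libraries by chance would give both, so the calls are not separate observations. The lower level did not rest on saline replicate 2 alone, as the median without it was -0.23 (camera adjusted p = 0.00553 at the preset correlation, range over settings up to 0.0245). Saline replicates 1 and 3, then left, scored 0.03 and -0.36, so this does not show a fall across the saline group. A GC content or transcript length trend did not account for the lower level either, with a median of -0.25 after the correction. Members did not fall by 1 common amount, as they differed beyond their errors (heterogeneity chi-square p = 0.000253, n = 20 genes, which are not independent replicates). This argues against a uniform loss of vessel cells only if vessel cells alone make these transcripts and the errors of the genes are independent. Neither was tested. Flt1 had a log2 fold change of -0.64 and Rgs5 of -0.38, while Vtn was at 0.03, Itm2a at 0.03 and Pdgfrb at 0.10. An uneven change in vessel cells or their transcripts with the group stays open and was not tested: saline replicate 1 scored 0.03 against -0.49 and -0.36 in the other saline libraries, the romidepsin libraries scored 0.21 and -0.22, and without romidepsin replicate 1 the higher level under the drug was not called (median 0.11).

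Tmem181b-ps was lower in both Shank3-deficient groups and passed in each, against the same wild-type libraries. Rabl2 stood lower in both without passing (adjusted p = 0.190 in saline against wild type and 0.232 with both groups joined, though 0.0343 in the former without wild-type replicate 3). Reads moved between the near-identical Tmem181 copies would leave their sum in place, but the summed counts of Tmem181a, Tmem181b-ps and Tmem181c-ps fell by 1.03 on the log2 scale in saline against wild type (adjusted p = 0.00101) and by a log2 fold change of -0.92 in romidepsin against wild type (adjusted p = 0.0195). Alignments that were not unique were not counted on genes. A loss of reads that became ambiguous between the copies would also lower the sum, and was not tested. DNA of the donor strain kept around Shank3 could lower Rabl2, 22.3 kb from it. With both Shank3-deficient groups joined, genes within 10 Mb of Shank3 were at an unadjusted p under 0.05 in 12 of 197 (6.09%), against 6.34% elsewhere (Fisher's exact p = 1). Of these 12, 7 were lower. Those between 89099097 and 89591960 were Rabl2, Mapk11, Dennd6b and Tubgcp6, lower (log2 fold changes -0.50, -0.35, -0.30 and -0.18), and Acr, higher (1.12). This interval runs from the start of Tubgcp6 to the end of Rabl2, so these genes themselves set it and it cannot show a cluster. Other tested genes inside it, among them Hdac10, Plxnb2, Sbf1 and Arsa, were not at an unadjusted p under 0.05. A window of 10 Mb can hide an excess close to Shank3, and no narrower window was tested. Donor DNA cannot be told apart from an effect of the deletion, since a short stretch of it would hold few genes. Tmem181b-ps lies on another chromosome, and a difference in copy number between the wild-type and mutant mice was not tested.

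The 6 wild-type and saline libraries can be split 10 ways into 3 against 3, which cannot give a share under 0.05. The real split called 1 gene and the highest other 20, and 4 of the 10 splits called at least 1. At an unadjusted p under 0.05 the real split gave 1242 genes and the highest other 1707. For gene lists the real split called 7 and the highest other 18, and 4 of the 10 called at least 7. The split that set wild-type replicates 1 and 2 with saline replicate 3 called the 20 genes, 4 of them meningeal (Fmod, Col1a2, Ptgds and Igf2). The split that set wild-type replicate 1 with saline replicates 1 and 2 called 17 genes, 10 of them oligodendrocyte markers such as Mag and Mobp. Both point to a structure of the samples in meningeal and myelin transcripts that crosses the groups.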
